A study of Anguilla anguilla with 24 samples.

How the data were processed

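RNA sequencing libraries were prepared from the brain and the liver of 12 European eels, 6 given a diet containing gold nanoparticles over 21 days and 6 kept as controls, which gave 24 libraries in 4 groups of 6. Each eel contributed a brain and a liver library, per the labels. Per the labels' protocols, total RNA was isolated with a silica column kit (SV Total RNA isolation system) and libraries were made with the TruSeq RNA kit, version 2. Whether eels of a group shared a tank is not given in the sources used here, so p-values measure the spread between individual eels within these groups.

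The deposited values were raw read counts per contig of a transcriptome assembly, with no normalization by the authors, as judged from whole numbers with a different total in each library. BWA 0.7.12 and SAMtools 1.1 were used upstream, per the submitters' processing notes. The assembly, its annotation, the counting rule, the strandedness and any filter on contigs are not given in the sources used here. The table held 50640 contigs, and each had at least 9 reads in at least 1 library. All 24 columns were matched to samples by the sample descriptions, and 0 columns belonged to no sample of the series.

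A contig label consists of a name and, where several contigs share it, a copy number and a number of copies (agpat3.1.2 is copy 1 of 2). Of the contigs, 16042 carried a gene or protein name, 10266 an NCBI locus number beginning with LOC, 57 a locus tag and 24275 a contig number only. Names were used as the labels give them, in gene symbol or protein entry style. Of 9984 distinct names, 5277 (52.9%) equalled a symbol in the RefSeq gene table of the species in any letter case. Since 13417 contigs shared 4953 labels, reads of a gene could be split between contigs, and values of a contig with several copies are uncertain in that respect. No genome coordinates were used.

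Libraries held between 50.3 and 116 M (mega) counted reads. Mean depth was 77.8 ± 7.87 M (SD, n = 6) in control brain, 96.6 ± 15.0 M in gold-fed brain, 70.2 ± 11.3 M in control liver and 69.3 ± 12.4 M in gold-fed liver. At these depths 1 read in a library of 70.2 M is far below 1 CPM, so biological spread rather than counting error limited most comparisons. No replicate pair was a duplicate, since the lowest chi-square per degree of freedom between libraries of a group was 66.7 in control brain, 73.4 in gold-fed brain, 151 in control liver and 216 in gold-fed liver, over contigs with at least 20 summed reads.

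Tests used edgeR 4.0.16 (quasi-likelihood F test, TMM factors, filterByExpr by group) in R 4.3.3, with Benjamini-Hochberg adjustment and a threshold of 0.05 on the adjusted p. Gold-fed and control eels were compared within each tissue, in a fit of 12 libraries without covariates. The difference between the gold responses of liver and brain was tested as an interaction in a fit of all 24 libraries, and liver was compared with brain in the 6 control eels. Standard errors of log2 fold changes were derived from the F statistic. All tests were two-sided.

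Gene groups were 35 lists of 1000 distinct gene symbols, of which 500 matched at least 1 contig by symbol, teleost copy suffix or a written map of protein entry names. The 31 lists with at least 5 measured contigs were tested with camera of limma 3.58.1 on voom values with a preset correlation of 0.01. The lists of antigen presentation (4 contigs), NOD-like receptors (3 contigs), pancreas (1 contig) and pituitary with pineal and retina (1 contig) were too small and were not tested for gold exposure. Camera with an estimated correlation, fry, and an exact permutation test of each list's mean log2(CPM + 0.5) per eel (924 arrangements, smallest possible p 0.00216) were run beside it. Added after the data were seen were the exact test and its values without each eel, the list test of the difference between tissues, the overlap at an unadjusted p, the fit restricted to at least 1 CPM in both tissues, the values of single contigs under the other count filters, and the tests of technical explanations with their splits of the eels. The groups, main tests, lists, naming rule and the other alternatives were fixed before the data were examined.

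Genes were named by rule. Where fewer than 5 contigs passed in a direction, the 5 named contigs of smallest p in that direction were given as values. For the difference between tissues the 5 named contigs of smallest p in each direction were used, and for liver against brain the 10 largest changes in each direction among contigs with a mean of at least 100 CPM. Metallothionein, haem oxygenase, heat shock protein, superoxide dismutase, catalase and cytochrome P450 contigs were named for context. Up to 4 members of smallest p of each list that passed were named after their values were seen, and some members are not reported here. At most 2 contigs without a gene name were printed per direction and comparison.

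Alternatives were DESeq2 1.42.0, limma-voom with and without library quality weights, RLE factors, library totals, other count filters, robust dispersion, a surrogate variable from sva 3.50.0, counts summed by label, a fit of all 24 libraries, the eel as a block, and leaving out each eel in turn. The eel numbers pair the brain and liver libraries, since the labels name the same animals. Over 41219 contigs the liver and brain deviations of an eel from their group means correlated at 0.321 to 0.535, and 12 of 12 livers correlated best with the brain of the same eel.

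The procedure was tested on simulated counts with 100 contigs changed at each fold. For the liver comparison edgeR recovered 2 of 100 contigs changed 2-fold and 56 of 100 changed 4-fold, with 1 false call among 42138 contigs. For the brain comparison it recovered 38 and 83 of 100, with 3 false calls among 49902. For the interaction it recovered 1 and 43 of 100, with 1 false call among 50484 (0 and 31 of 100, with 5 false calls, with the eel as a block), and for liver against brain 15 and 74 of 100, with 3 false calls among 50088. The simulated livers and brains shared no differences between eels, so these counts cannot weigh the block against the fit without it. For liver against brain most simulated contigs were unchanged, whereas most real contigs differed, so its recovered and false calls need not carry over. DESeq2 recovered 17 and 81 of 100 in liver with 41 false calls, and 63 and 94 of 100 in brain with 78 false calls. In a simulated liver comparison a list of 31 contigs raised 1.5-fold passed camera with the preset correlation at an adjusted p of 6.18e-17, and 0 other lists passed. With an estimated correlation its adjusted p was 2.69e-04. The simulated contigs varied independently of each other, so this cannot show how often the preset correlation calls lists of correlated contigs.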

Results

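Gene expression was measured by RNA sequencing in the liver and brain of 12 European eels (Anguilla anguilla). Of these eels, 6 received gold nanoparticles, particles of metallic gold of nanometre size, through their food over 21 days, and 6 were controls. The series asks which transcripts respond to this dietary exposure in each tissue. Each of the 4 groups held 6 libraries, with 66.0 to 85.3 M counted reads (M, mega) in control brain, 79.3 to 116 M in gold-fed brain, 59.4 to 89.8 M in control liver and 50.3 to 87.6 M in gold-fed liver. Values are normalised CPM per contig as mean ± SD over 6 eels.

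Liver and brain of the control eels differed in most transcripts, and the leading genes were those of each tissue. Highest in liver relative to brain were the fucose-binding lectins FUCL4.3.3 (log2 fold change 11.99), FUCL7.1.5 and FUCL3.4.4, lysozyme LYSC.1.2 (11.64), the coagulation inhibitors serpind1.1.2 (11.48) and proc (11.37), the lipogenic factor thrsp.2.2 (11.44) and complement c4 (11.26), together with lemd3.3.3 and msmb. Highest in brain were the synaptic genes syn2.4.4 (log2 fold change, liver over brain, -6.96), gria2.3.3, AP180.2.2 and VGLU2 (-6.65), the astroglial filament GFAP (-6.80), the myelin protein myp0.1.2, and ALDOC, ckbb, stmn3 and CBPE. Levels of the lectins varied between control livers, and FUCL4.3.3 ranged from 0.932 to 1799 CPM. The log2 fold change was 10.38 for FUCL4.3.3 and 10.88 for LYSC.1.2 without eel 6, and 10.37 for FUCL3.4.4 without eel 4 (11.34 with all eels). All 65 hepatocyte contigs and all 42 complement and acute phase contigs were higher in liver, and all 30 neuron contigs were higher in brain. Among the synaptic contigs, 80 of 87 were higher in brain and 4 in liver, and of the glial contigs 13 of 15 were higher in brain. Erythrocyte contigs were higher in liver for 16 of 20 and in brain for 1, and biliary and intestinal contigs were higher in liver for 12 of 15 and in brain for 3.

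In all, 37344 of 49741 contigs passed between the tissues of control eels with edgeR, 17381 higher in liver and 19963 higher in brain. With library totals alone as the scaling, 44234 passed, 5410 higher in liver and 38824 higher in brain, so the split between directions depended on the scaling. The tissue fold changes given above used TMM factors, and their sizes shift with the scaling, as the list counts can. The axis separating the tissues carried 79.0% of the variance of all libraries. Summed hepatocyte markers in brain stood at 0.270% of their liver level in control and 0.271% in gold-fed eels. Neuron markers in liver stood at 0.635% of their brain level in control and 0.759% in gold-fed eels.

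**Figure D1:**
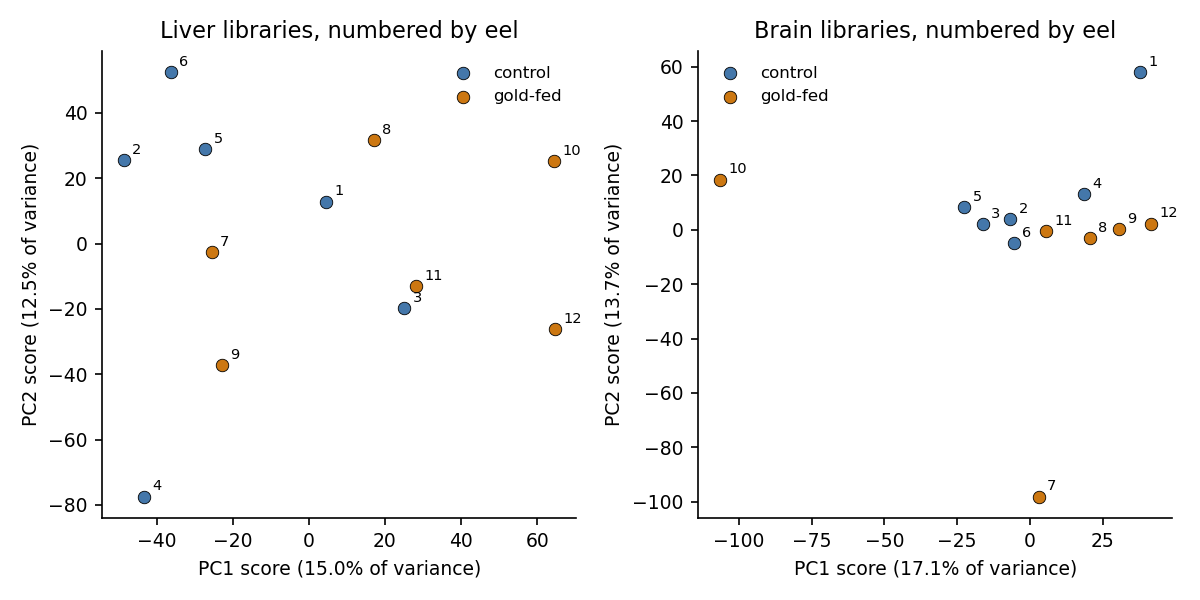
Principal component scores of the liver libraries (left) and the brain libraries (right), each point 1 eel, numbered by eel and coloured by group, with the share of variance on each axis. The mean score of gold-fed livers on the first component lies 41.9 above that of control livers (exact permutation p 0.0628), and the brain of eel 10 lies at -106.51 on the first brain component, away from the other gold-fed brains at 3.01 to 41.5.

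Among the named liver contigs the smallest p belonged to agpat3.1.2, an acyltransferase of phospholipid synthesis, at 15.7 ± 3.14 CPM in controls and 46.1 ± 12.8 CPM in gold-fed eels (log2 fold change 1.55, SE 0.21, n = 6). The lowest gold-fed liver, at 33.7 CPM, was above the highest control liver, at 20.03 CPM. Named contigs with lower values in gold-fed livers included cd3z.2.2, the zeta chain of the T cell receptor complex. Its level was 2.27 ± 0.535 CPM in controls and 0.485 ± 0.252 CPM in gold-fed eels (log2 fold change -2.23, SE 0.35). The contig cd247, also named for this chain, had 1.08 ± 0.184 and 0.909 ± 0.289 CPM (log2 fold change -0.25, SE 0.23). A fall of the size seen for cd3z.2.2 was thus not shared by cd247. The endosomal tetraspanin cd63 had 3.97 ± 1.44 and 1.14 ± 0.333 CPM, and pleckstrin (plek), a kinase substrate of blood cells, had 5.32 ± 0.877 and 2.64 ± 0.435 CPM. None of these passed the adjusted threshold in edgeR, where the adjusted p of agpat3.1.2 was 0.0651 and those of cd3z.2.2, cd63 and plek were 0.201.

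The other named liver contigs of smallest p with higher values in gold-fed eels were the developmental zinc finger gene sall1.2.2 (log2 fold change 0.89), the cadherin cdh4.1.2 (2.46), the transcription factor SOX9A (1.62) and AVR2A (2.30). Those with lower values were CH25H, a hydroxylase of cholesterol (-1.77), and ARP2 (-2.28). Contigs without a gene name included contig_17929 (2.56) and contig_01539 (2.47), and on the lower side LOC106606884 (-1.62) and LOC105012780 (-2.08). Genes often used as markers of metal and oxidative stress did not pass. The metallothionein MTA had 846 ± 409 CPM in control and 518 ± 292 CPM in gold-fed livers (log2 fold change -0.71, SE 0.37, adjusted p 0.631). Log2 fold changes were -0.52 for haem oxygenase hmox1, -0.13 for superoxide dismutase sod1.3.3 (another contig of this label, sod1.1.3, had -1.14), -0.25 for the catalase contig CATA and -0.29 for the pollutant-inducible cytochrome CP1A1.2.2. For the chaperone HSP70.2.2 the log2 fold change was -0.07, and its sign turned without control liver 1 (0.01), control liver 6 (0.02), gold-fed liver 9 (0.02) or gold-fed liver 12 (8.9e-04).

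With edgeR, 0 of 41793 liver contigs passed, while 3512 (8.40%) had an unadjusted p below 0.05 against 2090 expected, 1841 of them higher and 1671 lower in gold-fed eels. DESeq2 called 280 contigs (88 higher, 192 lower), limma-voom called 0, and an edgeR fit of all 24 libraries called 229 (89 higher, 140 lower). The fit of all libraries shares 1 spread between liver and brain. It put 7141 of 50455 contigs at an unadjusted p below 0.05 in liver and 1819 in brain, against 2523 expected in each. Its liver calls are therefore less reliable than those of the liver fit. The 10 named contigs of smallest p, among them agpat3.1.2 and cd3z.2.2, were among the calls of DESeq2 and of the fit of all libraries. Without control liver 1, 3 contigs passed, all lower in gold-fed eels, including cd63 (adjusted p 0.0270). On the first principal component of the liver libraries (14.96% of variance) the groups differed with an exact permutation p of 0.0628 (adjusted p 0.251 over 4 tests).

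**Figure D2:**
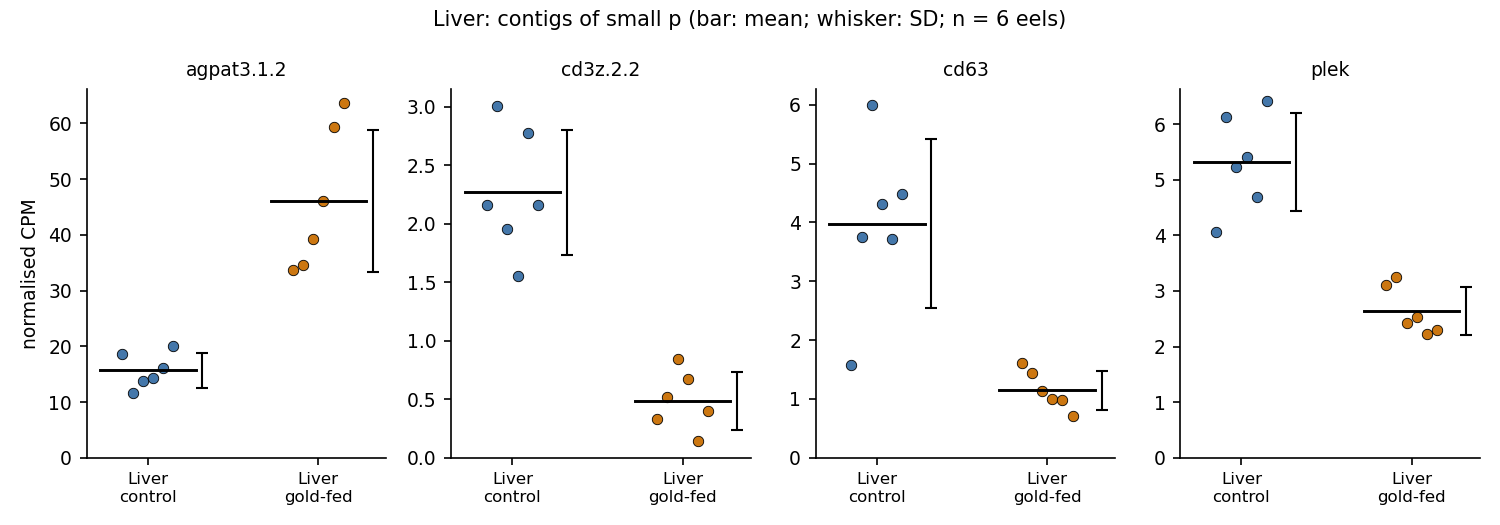
Normalised CPM of agpat3.1.2, cd3z.2.2, cd63 and plek in control and gold-fed livers, each point 1 eel, with the mean as a bar and the SD as a whisker (n = 6). All 6 gold-fed livers lie above all 6 control livers for agpat3.1.2 and below them for cd3z.2.2 and plek.

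Among the fixed gene lists in liver, cholesterol and bile acid metabolism rose in gold-fed eels by camera with the preset correlation, with 25 of 30 contigs higher and 5 lower (median log2 fold change 0.62, adjusted p 6.18e-06). Its call was lost with an adjusted p = 0.650 with an estimated correlation. Over the list alone, 7 contigs passed (adjusted over the list alone) against 0 when adjusted over all contigs. Examples were the sterol regulator srebf2.5.5 (4.81 ± 0.878 and 11.2 ± 6.75 CPM in control and gold-fed livers, log2 fold change 1.22), the lipoprotein receptor ldlr.2.3 (64.1 ± 24.7 and 122 ± 44.0 CPM, 0.93), lanosterol synthase lss (1.72) and squalene synthase fdft1.2.2 (1.90). The values of fdft1.2.2 and lss rested in part on gold-fed liver 11, at 104 CPM of fdft1.2.2 against 7.88 to 17.7 CPM in the other gold-fed livers, and were 0.75 and 0.96 without it. The list's mean score per eel differed by 0.52 (log2) with an exact permutation p of 0.0346, adjusted p 0.537, and by 0.33 without gold-fed liver 11 (exact permutation p 0.0714), and the largest exact p without 1 eel was 0.0887 (without control liver 3).

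Blood cell lists lay in the other direction in liver. Markers of B and T cells fell, with 9 of 9 contigs lower (median log2 fold change -0.90, camera adjusted p 4.56e-06), and the adjusted p = 0.409 with an estimated correlation. These 9 contigs carried 4 labels, and most were copies of the single label ptprc, so the count of contigs is not a count of genes. The B cell factor of the list, pax5, was not among them, so no B cell marker was measured in liver. Examples were the pan-leukocyte phosphatase ptprc.4.6 (4.47 ± 2.39 and 1.90 ± 0.545 CPM, log2 fold change -1.23) and the T cell kinase lck (-0.90). Others were the lymphoid factor ikzf1 (-0.92) and the T cell receptor zeta chain contig cd247 (-0.25). The exact permutation p of the score per eel was 0.0152, adjusted p 0.470. Markers of macrophages and neutrophils fell, with 7 of 11 contigs lower (median -0.44, adjusted p 0.00326), and the adjusted p = 0.650 with an estimated correlation. Among them the integrin itgb2.2.2 had a log2 fold change of -1.13, the myeloid factor spi1 of -0.82, cd68.1.2 of -0.46 and nccrp1 of -0.44. Erythrocyte markers fell, with 18 of 20 contigs lower (median -0.30, adjusted p 0.0392), and the adjusted p = 0.865 with an estimated correlation, with rhag at -0.73 and the globins HBAC.2.2 at -0.65 and HBAA.1.2 at -0.56. Adjusted over the list alone, 1 B and T cell contig, 1 macrophage and neutrophil contig and 0 erythrocyte contigs passed.

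Smaller shifts were found in 3 further liver lists. Oxidative stress and glutathione genes fell, with 28 of 38 contigs lower (median -0.17, camera adjusted p 0.00450), and the adjusted p = 0.650 with an estimated correlation, with gstk1.2.3 at -1.04, sod1.1.3 at -1.14, txnrd3 at -0.50 and sod2.1.2 at -0.40. Ribosomal protein genes fell, with 132 of 191 contigs lower (median -0.07, adjusted p 0.0252), and the adjusted p = 0.865 with an estimated correlation, with RS20.1.2 at -0.73 and RS6.2.3 at -0.38 but RPS13.4.4 at 2.56, a value that was 0.71 without gold-fed liver 10 and 3.34 without control liver 2. Oxidative phosphorylation genes fell, with 40 of 49 contigs lower (median -0.15, adjusted p 0.0332), and the adjusted p = 0.865 with an estimated correlation, with COX6A.1.4 at -1.53 (-0.76 without control liver 1), SDHB at -0.44 and ndufs4.1.2 at -0.33 but atp5f1.3.3 at 1.97. Adjusted over the list alone, 1 oxidative stress contig, 0 ribosomal contigs and 0 oxidative phosphorylation contigs passed.

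Of the 31 lists, 7 passed in liver with the preset correlation, 1 up and 6 down, and 0 with an estimated correlation, with fry or with the exact permutation test per eel, whose smallest adjusted p were 0.409, 0.196 and 0.470. The estimated correlations within these 7 lists were 0.111 to 0.584, far above the preset 0.01. Camera p-values with the preset correlation thus overstate the evidence. As many as 7 liver lists passed in 29 of 100 splits of the eels, the real one included. Unadjusted exact permutation p were 0.242 for macrophages and neutrophils, 0.141 for oxidative stress and 0.418 for erythrocytes. They were 0.532 for ribosomal proteins and 0.370 for oxidative phosphorylation. The cholesterol, B and T cell, and macrophage lists passed in each of the 12 fits without 1 eel. With counts summed by label, ribosomal proteins (0.388) and erythrocytes (0.449) no longer passed, and the B and T cell list, with 4 labels, was too small to test. Without control liver 6 the count was 3, and oxidative stress (0.0827), ribosomal proteins (0.172), oxidative phosphorylation (0.296) and erythrocytes (0.418) no longer passed. Without gold-fed liver 9 the count was 4, with adjusted p of 0.610 for ribosomal proteins, 0.135 for oxidative phosphorylation and 0.127 for erythrocytes. Ribosomal proteins also no longer passed without control liver 2 (0.429) or 3 (0.894) or gold-fed liver 8 (0.297). The same held for oxidative phosphorylation without control liver 2 (0.496) or 5 (0.144) or gold-fed liver 12 (0.0669), and for erythrocytes without control liver 1 (0.342) or gold-fed liver 8 (0.237) or 11 (0.539).

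**Figure D3:**
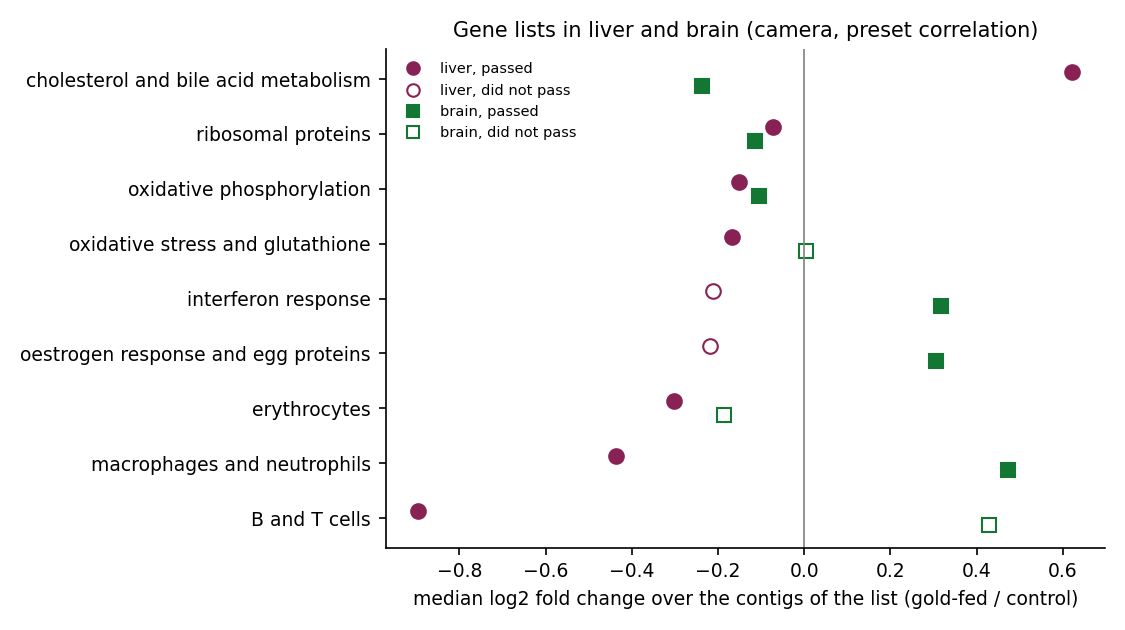
Median log2 fold change (gold-fed over control) over the contigs of each list that passed camera with the preset correlation in liver or brain, with circles for liver and squares for brain and filled symbols for lists that passed. Cholesterol and bile acid metabolism lies at 0.62 in liver and at -0.24 in brain, and B and T cell markers lie at -0.90 in liver.

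In brain a single contig rose in gold-fed eels, LOC106611841.2.3, a locus without a gene name. It had 0.0416 ± 0.0387 CPM in control and 2.64 ± 0.913 CPM in gold-fed brains (log2 fold change 5.97, SE 0.48, edgeR adjusted p 0.00104, n = 6), higher in 6 of 6 gold-fed brains. Control brains held at most 8 reads of it and gold-fed brains 130 to 388. Reads were present in 0 of 6 control livers and 5 of 6 gold-fed livers, at 10 reads or fewer per liver. The other contigs of this label did not pass, with log2 fold changes of 0.20 for LOC106611841.1.3 and -1.34 for LOC106611841.3.3 (7.42 ± 2.95 and 2.94 ± 2.14 CPM). When the counts of the label were summed the difference was -0.03 (adjusted p 0.974), so the call was absent at the level of the label.

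Among named brain contigs the smallest p belonged to mapre3.3.4, a microtubule end-binding protein, at 17.9 ± 2.59 CPM in control and 11.5 ± 0.426 CPM in gold-fed brains (log2 fold change -0.64, SE 0.10, adjusted p 0.165), and to the circadian clock gene per3.3.5, at 31.4 ± 10.9 and 13.4 ± 1.76 CPM (-1.23, SE 0.20, adjusted p 0.208). The lysosomal scaffold lamtor3.3.4 had 3.83 ± 1.75 and 12.9 ± 4.91 CPM (1.75, SE 0.32, adjusted p 0.329). These values did not pass in edgeR. Further named contigs with higher values in gold-fed brains were the guanylate kinase guk1.1.2 (0.50), the secretory granule protein ptprn.1.2 (0.43), snapc5 (0.27) and fam162a (0.24). Lower values were found for kiaa1107.2.2 (-1.09), the ribosomal protein contig RPS26.3.3 (-0.81) and the endosomal adaptor appl2 (-1.10). Of the context genes, MTA had a log2 fold change of -0.20, HSP70.2.2 of -0.19, sod1.3.3 of 0.12 and CP1A1.2.2 of -0.16. Catalase (CATA) had 43.0 ± 2.34 and 43.1 ± 4.44 CPM (log2 fold change 0.00), and the sign was negative with limma-voom (-0.0044), with library totals (-0.02), and without control brain 1 (-0.02) or 2 (-0.01) or gold-fed brain 7 (-0.01) or 9 (-0.05). Without a gene name, contig_14544 had a log2 fold change of 2.19, contig_22698 of -0.97 and LOC103372676.3.3 of -0.46.

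With edgeR, 1 of 49830 brain contigs passed, and 3863 (7.75%) had an unadjusted p below 0.05, 1677 higher and 2186 lower. DESeq2 called 182 (70 higher, 112 lower), among them the 10 named brain contigs of smallest p, and LOC106611841.2.3 passed with edgeR, DESeq2 and limma-voom and in each of the 12 fits without 1 eel. The count was 2 without control brain 5 or gold-fed brain 8 and 4 without gold-fed brain 10.

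**Figure D4:**
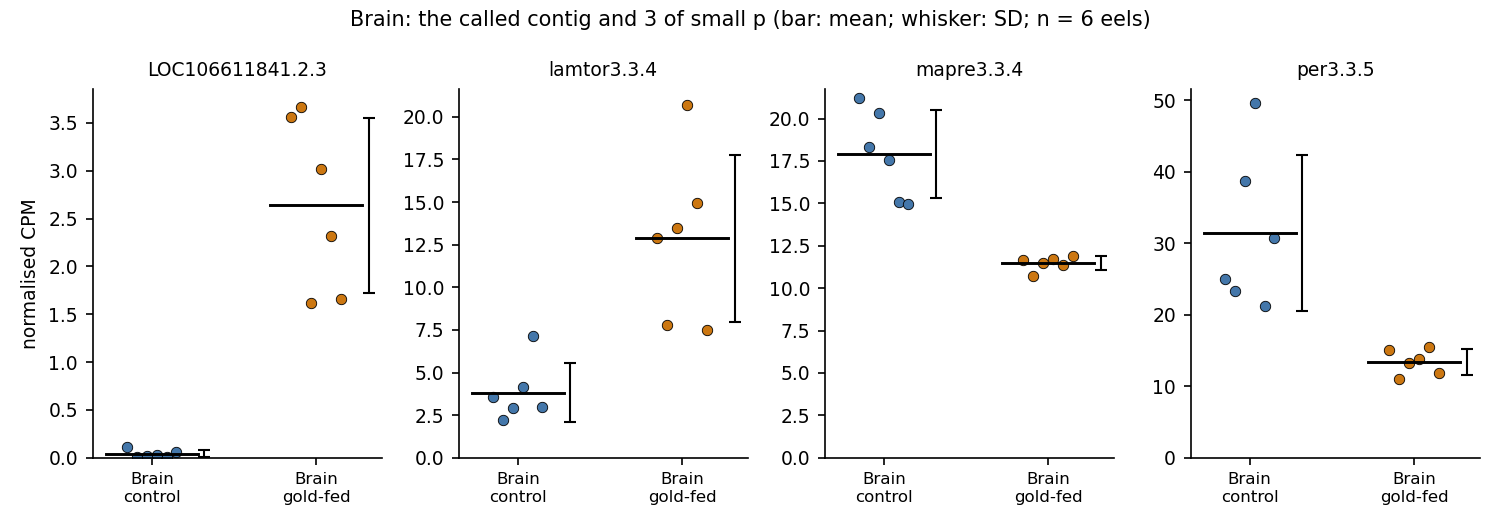
Normalised CPM of LOC106611841.2.3, lamtor3.3.4, mapre3.3.4 and per3.3.5 in control and gold-fed brains, each point 1 eel, with the mean as a bar and the SD as a whisker (n = 6). LOC106611841.2.3 is near 0 in control brains and at 1.61 to 3.67 CPM in gold-fed brains.

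In brain, genes of cholesterol and bile acid metabolism fell by camera with the preset correlation, with 23 of 29 contigs lower (median log2 fold change -0.24, adjusted p 8.17e-05), and the adjusted p = 0.606 with an estimated correlation. The sterol oxidase msmo1 had 33.2 ± 4.73 and 25.9 ± 4.41 CPM (log2 fold change -0.36), the sterol sensor INSI1 -0.24 and srebf2.4.5 -0.60. The score per eel differed by -0.17 (log2) with an exact permutation p of 0.00866, adjusted p 0.252, and by -0.13 (exact permutation p 0.0195) without gold-fed brain 10, which stood apart from the other gold-fed brains at 2.88 against 3.07 to 3.17. Ribosomal protein genes fell, with 128 of 191 contigs lower (median -0.11, adjusted p 8.17e-05), and the adjusted p = 0.643 with an estimated correlation, with RPS26.3.3 at -0.81, RS20.1.2 at -1.26, rps12.3.3 at -0.79 and RS13.4.8 at -0.72. Oxidative phosphorylation genes fell, with 38 of 49 contigs lower (median -0.11, adjusted p 2.56e-04), and the adjusted p = 0.606 with an estimated correlation, with ndufa2.2.2 at -0.65, NDUFA6 at -0.49, ATPA at -0.78 and ndufs7.3.4 at -0.36.

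Macrophage and neutrophil markers were higher in 11 of 11 contigs (median 0.47, camera adjusted p 0.0180), and the adjusted p = 0.656 with an estimated correlation. The lysosomal glycoprotein cd68.2.2 had 8.51 ± 4.36 and 20.03 ± 12.2 CPM (log2 fold change 1.24), itgb2.2.2 had 0.57, the microglial receptor csf1r 0.44 and lysozyme LYSC.2.2 1.14. Markers of B and T cells did not pass in brain, with 9 of 10 contigs higher (median 0.43, adjusted p 0.220), nor did erythrocyte markers, with 16 of 20 lower (median -0.19, adjusted p 0.0620). Interferon response genes rose, with 13 of 16 contigs higher (median 0.32, adjusted p 0.0352), and the adjusted p = 0.643 with an estimated correlation, with the antiviral GTPase MX1 at 1.00, and the RNA sensors ifih1 at 0.37 and dhx58.2.3 at 0.62. Oestrogen response genes rose, with 8 of 8 contigs higher (median 0.31, adjusted p 0.0180), and the adjusted p = 0.643 with an estimated correlation. The 8 contigs carried 4 labels, most of the contigs were copies of ESR2, and no egg protein of the list was matched. Here the androgen receptor ar had 0.17, the oestrogen receptor ESR2.4.5 0.35, the aromatase CP19A 0.32 and esr1 0.06. The sign of CP19A turned without gold-fed brain 8 (-0.08), and that of esr1 without control brain 3 (-0.01) or 4 (-0.01) or gold-fed brain 8 (-0.01). Adjusted over the list alone, 0 contigs passed in any of these 6 brain lists.

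Of the 31 lists, 6 passed in brain with the preset correlation, 3 up and 3 down, and 0 with an estimated correlation, with fry or with the exact permutation test per eel, whose smallest adjusted p were 0.606, 0.264 and 0.252. Unadjusted exact permutation p were 0.457 for interferon response, 0.325 for macrophages and neutrophils and 0.214 for oestrogen response. They were 0.0281 for ribosomal proteins and 0.0195 for oxidative phosphorylation. The cholesterol, ribosomal and oxidative phosphorylation lists passed in each of the 12 fits without 1 eel, and the count was 10 without control brain 1 or gold-fed brain 7. Macrophages and neutrophils no longer passed without control brain 3 (0.0636) or 5 (0.1298) or gold-fed brain 8 (0.0940), 9 (0.0794) or 12 (0.143), nor with counts summed by label (0.0734). Interferon response genes no longer passed without control brain 2 (0.199), 3 (0.127) or 5 (0.1298) or gold-fed brain 11 (0.148) or 12 (0.143), and oestrogen response genes without control brain 4 (0.0541) or 6 (0.0878) or gold-fed brain 8 (0.0940). With counts summed by label the oestrogen list, with 4 labels, was too small to test.

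The gold response differed between liver and brain for 3 contigs. The contig agpat3.1.2 was at 74.5 ± 6.78 and 75.1 ± 7.28 CPM in control and gold-fed brains against 15.7 ± 3.14 and 46.1 ± 12.8 CPM in the livers (difference of log2 fold changes 1.504, SE 0.22, edgeR adjusted p 0.0143). The unnamed contig_02561 had 1.71 ± 1.07 and 0.361 ± 0.0778 CPM in control and gold-fed livers and 21.7 ± 5.11 and 26.9 ± 4.54 CPM in brains (difference -2.59, SE 0.42, adjusted p 0.0376). The small GTPase rab38, known from pigment granule traffic, passed at an adjusted p of 0.00929, but it had 0 reads in all 6 control livers and 2 to 4 reads in the gold-fed livers, near the floor of 3 reads, so no fold is given for liver. Its brain values were 1.51 ± 0.392 and 1.36 ± 0.268 CPM. Further named contigs of small p did not pass, with differences of 2.45 for cdh4.1.2, -2.53 for ARP2, -1.94 for cd63, -1.80 for the T-box factor eomes and -2.93 for bcl11aa.1.2. The contig rangrf was at 13.7 ± 2.88 and 7.65 ± 0.977 CPM in control and gold-fed livers and at 32.2 ± 3.45 and 35.3 ± 3.51 CPM in brains (adjusted p 0.0649). For pde3a.1.2 and mat2a.1.6 all control livers were at 0 CPM.

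In total 3 of 50455 contigs passed, 2 toward liver and 1 toward brain, and 3419 had an unadjusted p below 0.05, while DESeq2 called 136 (49 toward liver, 87 toward brain). With the eel as a block, which uses the pairing of liver and brain, 1 contig passed, contig_02561, and the adjusted p was 0.0720 for agpat3.1.2 and 0.296 for rab38. Without eel 4 or eel 5 the count was 0, without eel 3, 11 or 12 it was 1, without eel 9 it was 5 and without eel 10 it was 6. The call of agpat3.1.2 ended without eel 3 (0.0611), 4 (0.0539), 5 (0.0895), 11 (0.0773) or 12 (0.0776), and that of rab38 without eel 4 (0.0539) or 5 (0.0656). The call of contig_02561 was kept without eel 1 or 6 and ended without eel 2 (0.133), 3 (0.0594), 4 (0.0558), 5 (0.139), 7 (0.0784), 8 (0.192), 9 (0.0760), 10 (0.0667), 11 (0.0935) or 12 (0.165), as well as with limma-voom (0.175), library totals (0.128), a surrogate variable (0.0602) and a mean of at least 1 CPM (0.0587).

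Gene lists with a different gold response in liver and brain were tested after the data were seen. Cholesterol and bile acid metabolism responded toward liver, with 26 of 30 contigs higher (median difference 0.82, camera adjusted p 1.05e-10), and the adjusted p = 0.363 with an estimated correlation. Adjusted over the list alone, 12 of its contigs passed, and the exact permutation p per eel was 0.00866, adjusted p 0.268. Lists toward brain were B and T cells (10 of 10 contigs, median -1.48, adjusted p 1.20e-05), macrophages and neutrophils (11 of 11, -0.79, 1.57e-05), interferon response (13 of 16, -0.43, 7.09e-04) and oestrogen response (6 of 8, -0.54, 0.0197), each with an adjusted p = 0.363 with an estimated correlation. Most contigs of the B and T cell list were copies of ptprc, and most of the oestrogen list were copies of ESR2. Oxidative stress genes were also toward brain (28 of 38, -0.14, 0.0263), with an adjusted p = 0.488 with an estimated correlation. Adjusted over the list alone, 1 macrophage contig, 1 interferon contig and 0 contigs of the other 3 lists passed. The smallest adjusted p was 0.386 with fry. Oestrogen response genes no longer passed without eel 4 (0.0507), 6 (0.0774) or 11 (0.0614), and oxidative stress genes without eel 2 (0.178), 5 (0.0854), 6 (0.223), 9 (0.107) or 12 (0.0813).

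**Figure D5:**
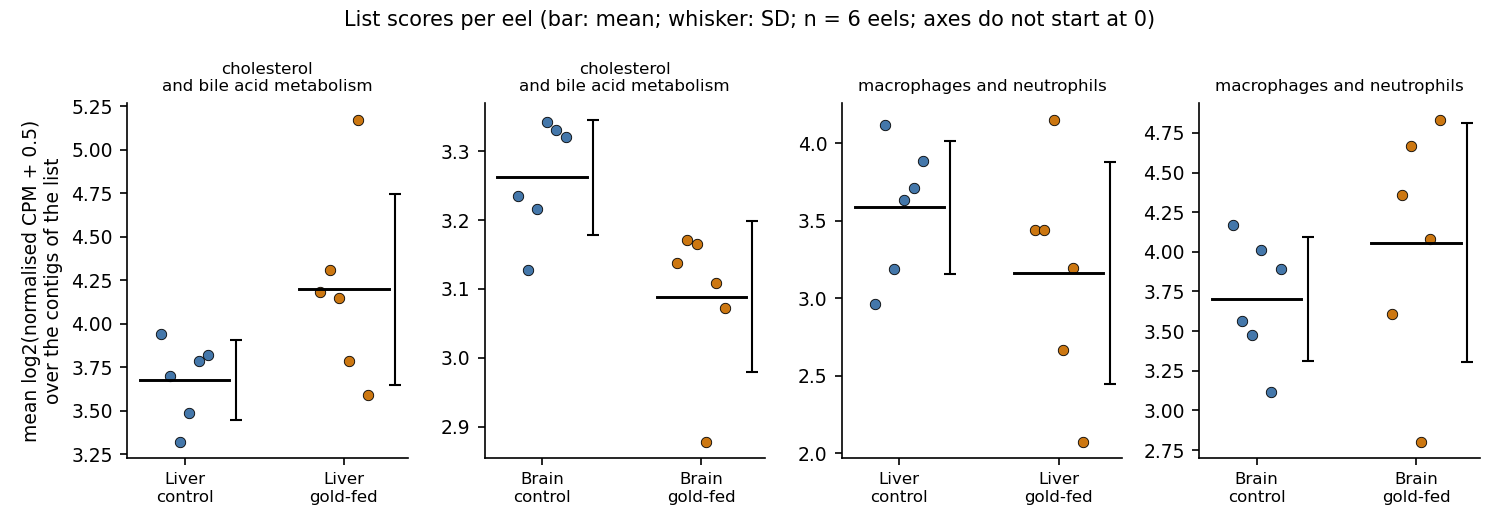
Mean log2(normalised CPM + 0.5) over the contigs of the cholesterol and bile acid list and of the macrophage and neutrophil list in liver and brain, each point 1 eel, with the mean as a bar and the SD as a whisker (n = 6, axes not starting at 0). The cholesterol score is 3.68 in control and 4.199 in gold-fed livers and 3.26 in control and 3.09 in gold-fed brains.

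Among 41219 contigs tested in both tissues, 0 passed in both with edgeR, and 14 with DESeq2. At an unadjusted p below 0.05, 239 contigs were higher in gold-fed eels in both tissues and 259 were lower in both. In opposite directions, 25 contigs were higher in liver and lower in brain and 27 the other way. The log2 fold changes of liver and brain correlated across contigs at r = 0.364, where contigs are not independent replicates and the tissues come from the same eels. Of the 10 named brain contigs of smallest p, 5 had liver means that differed in the same direction as in brain (lamtor3.3.4, guk1.1.2, mapre3.3.4, per3.3.5 and RPS26.3.3) and 5 in the opposite direction (ptprn.1.2, snapc5, fam162a, kiaa1107.2.2 and appl2). For per3.3.5 the control livers ranged from 12.7 to 43.1 CPM and the gold-fed livers from 6.29 to 12.8 CPM, and for lamtor3.3.4 from 0.992 to 2.76 and from 2.28 to 6.30 CPM. The fam162a contig, higher in gold-fed brains, had a mean of 26.8 CPM in control and 25.0 CPM in gold-fed livers, and appl2 lay near 0 reads in liver.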

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

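Both tests on LOC106611841.2.3, the split counts and the overlap at an unadjusted p, the exact permutation test of lists and the list tests of the difference between tissues were chosen only after the result was seen, and the leukocyte genes were chosen after the B and T cell result but before their own values were seen. The erythrocyte difference and the correlation of tissues within eels were known before their tests were set. A library stood apart from the other 5 of its group, by the ratio of its gap to the group's range, in 22 of 278 groups of values, where chance gives 1 in 20 (13.9 groups). CPM values here are normalised within each tissue. Control brain 4 accounted for 5 of these, with 64.3 CPM of snapc5, 1.07 of appl2, 7.78 of lemd3.3.3, 325 of syn2.4.4 and 1311 of ckbb. Gold-fed brain 10 accounted for 3, with 4.18 CPM of mat2a.1.6, a score of 2.88 (mean log2 CPM) for cholesterol and bile acid metabolism and -106.51 on the first principal component. Among the other brains, control brain 3 had 10.5 CPM of RPS26.3.3 and 1.21 of ndufa2.2.2, control brain 1 had 297 of AP180.2.2 and 2.201 of contig_07250, and gold-fed brain 12 had 21.3 of ifih1 and 23.4 of dhx58.2.3. In control livers, liver 4 had 19.3 CPM of rangrf and 2122 of lemd3.3.3, liver 2 had 2.02 of myp0.1.2, liver 1 had 42.1 of rhag and liver 6 had 0.133 of contig_17929. In gold-fed livers, liver 8 had 1108 CPM of MTA against 333 to 458 in the others, liver 11 had 104 of fdft1.2.2 and liver 10 had 9.84 of SDHB.

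The gold response differed between liver and brain (liver minus brain, log2) for agpat3.1.2 by 1.504, for contig_02561 by -2.59 and for rab38 by a fitted 6.45 that rests on livers at or near 0 reads. With the eel as a block the adjusted p was 0.0720 for agpat3.1.2 and 0.296 for rab38, and of the 3 contigs contig_02561 alone passed. For lists that passed camera with the preset correlation the median difference was 0.82 for cholesterol and bile acid metabolism, -1.48 for B and T cell markers, -0.79 for macrophages and neutrophils, -0.43 for interferon response, -0.54 for oestrogen response and -0.14 for oxidative stress and glutathione. None of these 6 lists passed with an estimated correlation (adjusted p 0.363 to 0.488), fry (smallest 0.386) or the exact permutation test (smallest 0.268).

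Gold-fed and control eels differed in the same direction in liver and brain for 498 contigs at an unadjusted p below 0.05, and the log2 fold changes of the tissues correlated at 0.364 across contigs. Differences between individual eels that both tissues share account for a correlation of this size, since 91 of 100 splits of the 12 eels gave one as high, with a median of 0.426 over the other splits. Reads carried over between libraries of an eel are argued against only for the 22934 contigs of similar level in both tissues. The correlation there was 0.448, with 0.395 to 0.504 when 1 eel was left out. Other splits of the eels gave 0.405 to 0.578 for these contigs. Whether carry-over adds to the correlation among contigs of unlike level was not tested. The count of 498 was reached by 1 of 100 splits, the real one, with 475 as the highest of the others and 306 as their median. Chance is therefore less likely for this count at an unadjusted p, which was chosen after the result was seen. Contigs in opposite directions, 52, were also above their median of 16 over the other splits. With the correlation below its median, the count of 498 does not show closer agreement of the tissues than other splits give. Gold exposure, or another difference between the groups of eels, stays open for that count and was not tested further.

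The contig LOC106611841.2.3 was near 0 in control brains and present in all 6 gold-fed brains. The greater depth of gold-fed brains is argued against, since at the lowest gold-fed level the shallowest control brain would hold 106 reads, and control brains held at most 8. Reads of a gene shared out between contigs of a label stay open, because the sum over the 3 contigs of the label differed by -0.029 (log2, adjusted p 0.974) while LOC106611841.3.3 differed by -1.34. Such sharing could follow sequence variants that differ between the groups of eels, which was not tested, and a response to gold exposure also stays open. Chance is not excluded for the brain count of 1, which 5 of 100 splits reached, with 2 as the highest of the others.

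B and T cell markers, mostly copies of ptprc, were lower in gold-fed livers, with a difference of -0.64 in mean log2 CPM. Their list passed camera with the preset correlation but not with an estimated one (adjusted p 0.409), fry (0.196) or the exact permutation test (0.470). Less blood in the sampled liver is argued against, since the difference was -0.73 with the erythrocyte score as a covariate (permutation p 0.0108), and -0.83 to -0.67 when 1 eel was left out. A candidate explanation is a lower share of leukocytes among the liver cells, for which 33 contigs of 26 leukocyte labels outside the lists were measured in the same eels. Their mean score differed by -0.50 (1.87 ± 0.253 in control and 1.37 ± 0.278 in gold-fed livers, exact permutation p 0.0130), with 29 contigs lower and 4 higher. Lower transcript levels per leukocyte and a response to gold exposure stay open and were not tested.

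Other splits of the same eels gave as many calls as the real split, the real one included, in these numbers. For liver lists it was 29 of 100 (7 real, 13 highest other), for brain lists 31 of 100 (6 real, 11 highest other) and for lists of the difference between tissues 57 of 100 (6 real, 14 highest other), so chance is not excluded for these. For liver contigs (3 highest other) and for the overlap (0 highest other) the real count was 0, which 100 of 100 splits reach by construction, so the splits show nothing about chance there. For contigs of the difference between tissues it was 3 of 100 (3 real, 4 highest other), so chance is less likely for that count but not excluded. For liver against brain it was 1 of 100 (37344 real, 1 highest other), the smallest share that 100 splits can give. Every other split there mixes the tissues in both groups, which by itself widens the spread and lowers the counts. Chance is less likely for that count but not excluded by the splits alone. The count of 3 comes from the fit without the eel as a block, and with the block, for which no splits were run, 1 contig passed. In the splits that swap the tissues within eels, which part as many pairs as the real one, 1 of 32 reached the real count. At an unadjusted p below 0.05 it was 3 of 100 in liver (3512 real, 3929 highest other), where chance is less likely but not excluded. In brain it was 7 of 100 (3863 real, 4880 highest other), where chance is not excluded either. At that p, 52 contigs moved in opposite directions in the tissues, a count that 4 of 100 splits reached (96 highest other, median 16 over the others). Chance is less likely for it but not excluded. With DESeq2 it was 1 of 30 in liver (280 real, 151 highest other), the smallest share that 30 splits can give, which makes chance less likely. In brain it was 3 of 30 (182 real, 314 highest other), where chance is not excluded. These shares were not adjusted for the number of counts examined.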

How the results depend on the processing

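The fit restricted to at least 1 CPM in both tissues, the exact permutation test of lists, its values without each eel and the list tests of the difference between tissues were chosen only after the result was seen. The cause of the differences below was not tested. At an adjusted p below 0.1, 3 contigs passed in liver, 3 in brain and 10 for the difference between tissues. DESeq2 called 280 in liver, 182 in brain, 136 for the difference and 14 in the overlap. With a mean of at least 1 CPM, 3 passed in liver and 1 for the difference, and with at least 1 CPM in both tissues 6 passed for the difference. The fit of all 24 libraries, which shares 1 spread between the tissues, called 229 in liver and 1 in the overlap. In brain a surrogate variable gave 2 and counts summed by label gave 0 (edgeR, smallest adjusted p 0.103). With the eel as a block 1 contig passed for the difference between tissues in place of 3, and the block changed no other count by over 1.5 times. Lists that passed numbered 0 in liver, 0 in brain and 0 for the difference with an estimated correlation, with fry and with the exact permutation test, in place of 7, 6 and 6 with camera. Leaving out 1 eel gave 0 to 3 contigs in liver, 1 to 4 in brain, 0 to 6 for the difference and 35656 to 36608 for liver against brain, and 3 to 8 lists in liver, 4 to 10 in brain and 5 to 8 for the difference. The count of 3 in liver came without control liver 1. For named contigs, 2133 values under an alternative kept their direction and side of the threshold, 67 passed only under the alternative, 22 no longer passed and 14 values near 0 changed sign, and for lists 229 kept both and 78 no longer passed. Depth limited contigs near 0 reads in liver, such as rab38.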

Other observations

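The camera tests in this part were fixed before the data were examined, but the adjustment over a list alone was not among the planned tests. The liver lists given here did not pass by camera with the preset correlation. Metallothionein and metal handling had a median log2 fold change of 0.09 over 34 contigs (adjusted p 0.959), heat shock genes of 0.06 (adjusted p 0.622) and xenobiotic metabolism of 0.12 (adjusted p 0.615). Interferon response genes had a median of -0.21 (adjusted p 0.0666), with 3 contigs that passed when adjusted over the list alone, and hepatocyte markers one of -0.02 (adjusted p 0.458). In brain, metallothionein and metal handling had a median of -0.03 (adjusted p 0.960), Toll-like receptor genes of 0.24 (adjusted p 0.0552), glial markers of -0.14 (adjusted p 0.0840) and synaptic genes of 0.04 (adjusted p 0.170). Circadian genes in brain had a median of -0.06 (adjusted p 0.207), and 1 contig of that list, per3.3.5, passed when adjusted over the list alone.

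On the second principal component of the brain libraries (13.7% of variance) gold-fed brain 7 had a score of -98.2.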
